A study of Mus musculus with 26 samples.

How the data were processed

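The series holds 26 samples of mouse liver cells, and 20 of them came with a scanner file, 1 array each. The other 6 samples are not analysed here. Used were 2 of 4 day 0 samples, 3 of 4, 3 of 4 and 3 of 3 YFP-negative samples at days 3, 7 and 14, and 4 of 4, 3 of 4 and 2 of 3 YFP-positive samples. Per the labels, RNA was isolated with Trizol and RNeasy, amplified with the NuGEN WT-Ovation Pico kit and labelled with Cy3 through the BioPrime Array CGH kit. The submitters' notes name Feature Extraction 9.53, while the headers of the scanner files name Feature Extraction 10.5.1.1 and design 014868 with 1 channel.

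The value taken from each scanner file was the processed signal, an intensity that is background-subtracted and detrended, holds surrogates for dim spots and is not normalized between arrays, per the file headers. The mean signal and the median background are intensity values as well, per the file headers. The deposited series-wide table of the authors gives a signed linear fold change of each sorted group against day 0, with a fall as minus the inverse, a false discovery rate in percent, and absent, marginal or present calls. The method behind it is not stated, and it was used only for comparison.

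Control spots and spots called outliers by the scanner software were left out, which left 43379 non-control spots and 41174 probes. Spots of one probe were averaged, and the log2 processed signal minus the 75th percentile of its array was used. The 39595 probes well above background on at least 2 arrays were kept, and for each gene the probe with the highest mean signal, giving 26650 genes, of which 8646 had several probes and 277 a missing value. The share of spots well above background ran from 81.0 to 91.2 percent (35147 to 39553 spots). Names were matched to the reference of GRCm38.p6, used for names only, with 16249 genes matched by accession (2313 of them renamed), 2385 by symbol, 859 by synonym and 7157 not matched. Positions are those of mm9 in the files. Foxl1, the driver of the recombinase, is not analysed here.

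The 7 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with moderated t-tests (2.32 prior and 13 residual degrees of freedom) and the Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. Other packages were data.table in version 1.17.8, jsonlite 2.0.0 and statmod 1.5.0. The 13 comparisons were YFP-positive against YFP-negative cells at each day and over the mean of days, each sorted group against day 0, day 14 against day 3 in each fraction, and the difference of the last 2. Gene lists, 17 with 290 genes of which 1 was not measured, were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 17 lists of a comparison. The lists of cell type markers were biliary and progenitor, hepatocyte, fetal liver, stellate and myofibroblast, endothelial, macrophage, lymphoid, neutrophil and erythroid. The lists of processes were cell cycle, epithelial junction, oxidative stress and heme, Notch, Wnt, Hedgehog, inflammatory signal, and immediate early and stress. Groups, comparisons, lists, the naming rule and most alternatives were chosen before the data were examined.

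Genes were named by rule. From each list and comparison came up to 4 members past the threshold with the largest change, plus the first member. For YFP-positive against YFP-negative cells came the 8 largest rises and falls past the threshold, well above background on every array of the higher group and without overlap of arrays, or for the mean of days with the same direction at each day. For the other comparisons came 5 and 5. Genes with only clone or predicted-gene identifiers were counted but not named, and a gene named in one comparison may appear in others. The result of 1 gene that the rule would name is not reported here. This rule was read further in 2 ways after values were seen. A list member counted as past the threshold with either adjustment, because few members passed over all genes. First members were given only for the mean of days, and Krt19 for each day, because of the other 204 values 8 passed and 96 that did not pass changed sign under at least 1 alternative. Where no array of the lower group was well above background, the fold change is given as a bound, "at least N-fold", taken against the lowest signal well above background on each of its arrays. That signal is the lowest of any such probe on the array, not a detection limit for the gene. The bound is thus nominal, and other processing gave smaller changes for some genes. The slide of each array was taken from the barcode in the name of its scanner file. Slides that held both groups of a comparison gave within-slide values, each of 1 array minus 1 array. These arrays are also part of the main fit. Where no slide held both groups, a fit with the slide as a fixed block rests on slide differences estimated from other groups.

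Alternatives tried were normexp background correction with an offset of 50, quantile normalization, no filter, a filter on the share of arrays, the mean of the probes of a gene, the slide as a random or a fixed block, the replicate number as a block, a trended and robust variance, array weights, a fit of only the groups compared, a minimum of 2-fold, camera with an estimated correlation, and leaving out each array. Another 4 were added after results were seen, namely leaving out YFP-positive day 3 arrays 3 and 4 together, days 7 and 14 alone, the macrophage list as a covariate, and probes across exon junctions only. The closing section gives their effect.

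The steps were tested on simulated data of 26373 genes, with 100 genes shifted per size. Changes of log2 2 and 4 were recovered in 28 and 64 percent of genes at day 3, 21 and 57 percent at day 7, 20 and 50 percent at day 14, and 52 and 87 percent over the mean of days. False calls were 7 of 99, 3 of 81, 7 of 77 and 18 of 157, so the share of false calls lay above 5 percent in 3 of the 4. The list step called the 1 shifted list of 20 and no other, also with an estimated correlation. Noise was drawn independently for each gene, so this check cannot show false list calls that arise when the genes of a list vary together.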

Results

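Gene expression was measured on Agilent 1-colour arrays in sorted liver cells of Foxl1-Cre; RosaYFP mice, in which cells with a history of the Foxl1-driven recombinase carry the yellow fluorescent protein YFP. Mice ate a diet with the liver toxin DDC for 3, 7 or 14 days. YFP-positive and YFP-negative cells were sorted from CD45-negative non-parenchymal cells, that is, liver cells other than hepatocytes and without the leukocyte surface protein CD45. The 20 arrays used here were 2 of day 0 (all non-parenchymal cells of chow-fed mice), 3, 3 and 3 of YFP-negative cells and 4, 3 and 2 of YFP-positive cells at days 3, 7 and 14. On the day 0 arrays 89.9 and 91.2 percent of the spots were well above background, and on the sorted arrays 81.0 to 88.3 percent. At these group sizes simulated changes of log2 4 between the fractions were recovered in 50 to 87 percent of genes. Values are log2 fold changes ± standard error, and adjusted p-values come from limma over 26650 genes unless another basis is named. Positions are those of the probe on the mm9 build. Gene lists were tested with camera, and their values are medians relative to the median of all genes unless they are given as fitted.

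The comparison of YFP-positive with YFP-negative cells averaged over the 3 days asked what sets the traced cells apart at any day of injury. The largest rise was that of Foxj1 (4.16 ± 0.85, 17.9-fold, adjusted p = 0.0391, chromosome 11, 116192214 to 116192273), the transcription factor of motile ciliated cells, and Dnali1, an axonemal dynein light chain, rose by 3.28 ± 0.58 (adjusted p = 0.0315). Uts2d, now Uts2b, a urotensin-related peptide, rose by 3.95 ± 0.80 (adjusted p = 0.0366), Ildr1, a protein of tricellular junctions, by 3.82 ± 0.74 (adjusted p = 0.0332), and the tight junction gene Cldn7 by 3.54 ± 0.73 (adjusted p = 0.0391). Tesc, which encodes a calcium-binding protein, rose by 3.44 ± 0.68 (adjusted p = 0.0350), the GABA receptor subunit gene Gabrp by 3.32 ± 0.68 and Bspry by 3.19 ± 0.66 (both with adjusted p = 0.0391). Each of these genes was higher in YFP-positive cells at all 3 days, which the naming rule required.

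Among the genes that were lower, Kcna5, a voltage-gated potassium channel, changed most (-6.07 ± 1.13, 67.4-fold, adjusted p = 0.0315, chromosome 6, 126482573 to 126482632). Mmrn1, a multimerin of platelets and endothelium (-5.21 ± 1.0, adjusted p = 0.0332), Dmp1, a matrix phosphoprotein (-5.18 ± 0.84, adjusted p = 0.0234), and Ccbe1, a secreted factor of lymphatic vessel growth (-5.16 ± 0.68, adjusted p = 0.00959), fell as well. So did Hs3st3a1, a heparan sulfate sulfotransferase (-5.13 ± 0.95, adjusted p = 0.0315), Astn2 (-5.12 ± 0.88, adjusted p = 0.0298), the netrin-G ligand gene Lrrc4c (-5.11 ± 0.78, adjusted p = 0.0170) and the stromal gene Islr (-5.10 ± 0.87, adjusted p = 0.0298). Each fell at all 3 days, which the naming rule required, although 1 of 3 other probes of Ccbe1 and the only other probe of Astn2 moved the opposite way.

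In all, 171 genes passed over the mean of days, 57 higher and 114 lower, and 44 of them carried only clone or predicted-gene identifiers. An unadjusted p under 0.05 by limma was found for 5699 genes. With normexp 7 of 43 calls were higher, and with quantile normalization 794 of 1107 were higher, so the share of higher genes is not settled by these data. The count also moved with single arrays. It was 1219 without YFP-positive day 3 array 3 and 297 without YFP-negative day 3 array 3. It fell to 23 without YFP-negative day 3 array 4, and to 19, 71 and 45 without YFP-negative day 7 arrays 1, 3 and 4. It was 20 and 52 without YFP-negative day 14 arrays 1 and 2, 50 and 90 without YFP-positive day 7 arrays 1 and 4, and 16 without YFP-positive day 14 array 1. With the slide as a fixed block 2 genes passed, and all 16 genes named above kept their sign without passing, whereas Tesc, Ccbe1 and Islr alone of the 16 passed with normexp. With days 7 and 14 alone 17 genes passed.

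**Figure D1:**
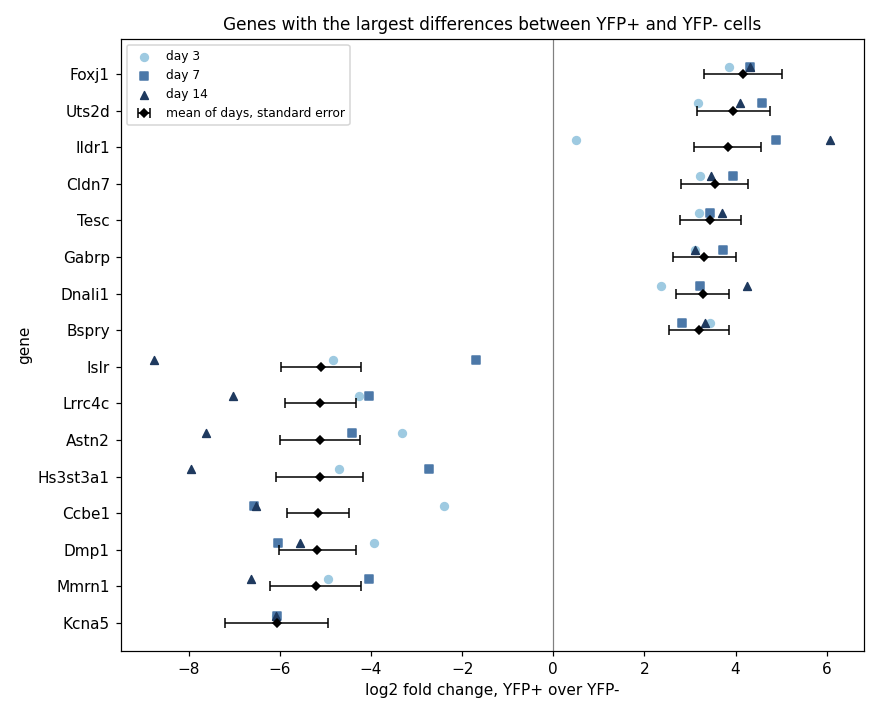
Log2 fold change of YFP-positive over YFP-negative cells for the 8 largest rises and 8 largest falls; diamonds are the mean of days with standard error and other markers the single days. Kcna5 lay lowest at -6.07 and Foxj1 highest at 4.16.

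Bile duct genes ran higher in YFP-positive cells as a list, with a median of 2.46 over the mean of days, and all 26 measured members were positive at each day. Cftr (2.48), Cldn7 and the epithelial transcription factor gene Ehf (2.61) rose over all genes, 3 members in total against 23 adjusted over the list alone. Those 23 included the cystic kidney gene Pkhd1 (3.67 ± 0.85), Krt19 (3.46 ± 0.79, adjusted p = 0.0555 over all genes and 0.00205 over the list alone, chromosome 11, 100002392 to 100002451), a keratin of bile ducts, and St14 (3.42 ± 0.75), a membrane protease gene. The camera test gave adjusted p = 1.79e-15 and adjusted p = 0.250 with an estimated correlation. As fitted, the median was 2.12 with the slide as a fixed block. Within slides that held both fractions, with 1 array of each, it was 3.66 relative to all genes at day 3 (slide 1) and 0.96 and 2.49 at day 7 (slides 4 and 7). The YFP-negative array of slide 1 had the lowest biliary mean of all arrays (-2.68).

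Stellate cell and myofibroblast genes ran lower by -2.38. Col1a1, the main fibrillar collagen gene (-4.95 ± 0.99, adjusted p = 0.0362, chromosome 11, 94813075 to 94813134), the keratan sulfate proteoglycan gene Lum (-4.01 ± 0.83, adjusted p = 0.0392), Reln (-3.34), Ngfr (-3.10), the retinol storage gene Lrat (-2.59 ± 0.42) and the smooth muscle gene Tagln (-2.24) fell over all genes. Adjusted over the list alone 20 members fell, among them Pdgfrb (-3.96 ± 1.09) and Col3a1 (-3.41 ± 0.83), while Gfap (0.95) and Rgs5 (0.92) rose. Acta2, the smooth muscle actin gene, stood at 0.08 ± 0.18 on its brightest probe, and its 4 other probes gave the opposite sign. The camera test gave adjusted p = 1.96e-13 and adjusted p = 0.178 with an estimated correlation. The fitted median was -1.96 with the slide as a fixed block, and within slides the list was lower by -0.24 at day 3 (slide 1) and by -1.81 and -1.70 at day 7 (slides 4 and 7).

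**Figure D2:**
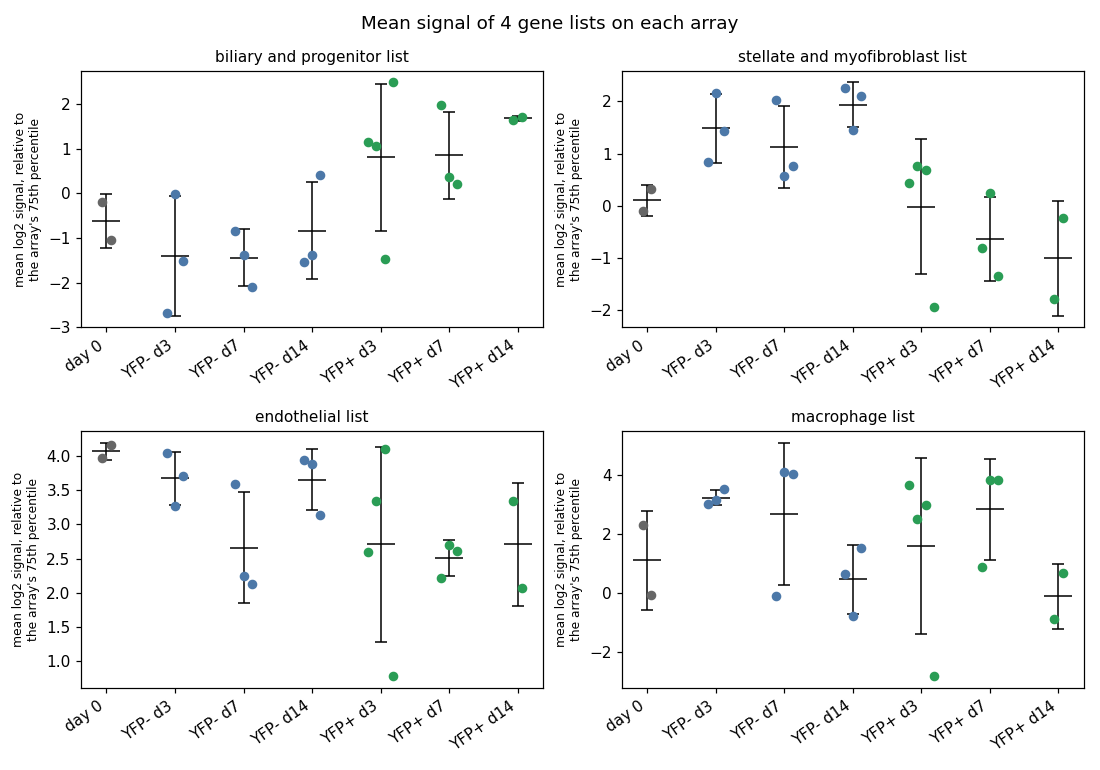
Mean log2 signal of 4 gene lists relative to the 75th percentile of each array; points are arrays, bars group means and whiskers standard deviations. The biliary list averaged 0.81 in YFP-positive and -1.40 in YFP-negative cells at day 3.

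Epithelial junction genes were higher by 2.27, with no member passing over all genes and 10 passing adjusted over the list alone. Crb3 (3.67 ± 0.86), Cldn2 (3.35 ± 0.91), Tjp3 (3.07 ± 0.97) and Cdh1 (2.78 ± 0.72), genes of cell polarity and of tight and adherens junctions, rose most by that measure. The list gave adjusted p = 1.57e-06 and adjusted p = 0.250 with an estimated correlation. Its fitted median was 2.26 with the slide as a fixed block, and within slides 1, 4 and 7 it was 3.31, 0.11 and 3.02 relative to all genes.

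The erythroid list was lower by -2.0, and 4 members fell adjusted over the list alone against 0 over all genes. Among these were the heme synthesis gene Alas2 (-3.94 ± 1.30) and the globin genes Hbb-b1, now Hbb-bt (-3.39 ± 1.06), and Hba-a1 (-2.94 ± 0.89). The list gave adjusted p = 0.00299 and adjusted p = 0.547 with an estimated correlation, and its direction turned with the slide as a fixed block, where the fitted median was -1.12 but the camera test pointed up. The call also ended without YFP-negative day 14 array 2 (-0.94 as fitted) and without YFP-positive day 14 array 2 (-1.31). Endothelial genes were lower by -0.69 without a member passing, Pecam1 among them (-1.19 ± 0.55), and the list gave adjusted p = 5.40e-05 and adjusted p = 0.547 with an estimated correlation. The endothelial fitted median was -0.56 with the slide as a fixed block, and within slides 1, 4 and 7 the list stood at -1.32, -0.80 and 0.84.

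Hal, a histidine-degrading enzyme of hepatocytes, fell by 4.21 on the log2 scale (-4.21 ± 1.06) adjusted over the list alone, while Alb stood at 0.05 ± 0.33 and the hepatocyte list at -0.79 (adjusted p = 0.0313, and adjusted p = 0.581 with an estimated correlation). Of the oxidative stress and heme list (-0.43), the glutathione peroxidase gene Gpx2 rose (2.12 ± 0.50) and Ugdh (-1.04 ± 0.26) and Nqo1 (-1.02 ± 0.31), both genes of detoxification, fell adjusted over the list alone, against 0 over all genes. That list gave adjusted p = 0.0198 and adjusted p = 0.250 with an estimated correlation. Its call ended with the slide as a fixed block (-0.26 as fitted) and without YFP-negative day 3 array 4 (-0.34) or day 7 array 3 (-0.31). Macrophage genes were lower by -0.71 and neutrophil genes by -1.16 without a member passing, with Emr1, now Adgre1, at -0.86 ± 1.24 and S100a8 at -1.81 ± 1.54. Each of these 2 lists gave adjusted p = 0.0313, with adjusted p = 0.688 and 0.581 with an estimated correlation. With the slide as a fixed block both turned upward, to fitted medians of 1.07 and 1.91, and the hepatocyte list turned as well (fitted median -0.13, test pointing up). Slide 5 held only YFP-positive day 3 array 4, the array with the lowest macrophage mean (-2.81). The fixed block thus takes this array out of the comparison. Leaving it out by itself turned none of these 3 lists (fitted medians -0.16 for macrophage, -1.01 for neutrophil and -0.50 for hepatocyte genes). The loss of that array alone therefore does not account for the turns. Slides 2, 3 and 5 held no YFP-negative array and slide 6 no YFP-positive array, so slide and fraction are partly confounded. Within slides 1, 4 and 7 the macrophage list stood at 0.66, 3.83 and -0.03 and the hepatocyte list at 1.45, -1.61 and 0.98. With normexp the hepatocyte (-0.56 as fitted), macrophage (-0.59) and neutrophil lists (-0.38) no longer passed, and with the macrophage list as a covariate the neutrophil list did not (-0.57). Single arrays ended these 3 calls as well. The fitted macrophage median was -0.16 without YFP-positive day 3 array 4, -0.37 without day 7 array 1 and -0.41 without day 14 array 1, and -0.64, -0.46, -0.47 and -0.51 without YFP-negative day 3 array 4, day 7 arrays 3 and 4 and day 14 array 3. The same arrays ended the neutrophil call (-1.01, -0.49, -0.81, -0.83, -0.84, -0.71 and -0.83 in that order), as did YFP-positive day 3 array 2 (-1.05). For the hepatocyte list they were YFP-negative day 3 array 4 (-0.47), day 7 array 3 (-0.49) and day 14 arrays 1 and 2 (-0.51 and -0.57), and YFP-positive day 3 arrays 2, 3 and 4 (-0.66, -0.69 and -0.50), day 7 arrays 1 and 3 (-0.57 and -0.61) and day 14 array 2 (-0.44).

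The other 7 lists did not pass over the mean of days, though with normexp the cell cycle and inflammatory signal lists did (fitted medians 0.28 and 0.28), and single members passed when adjusted over the list alone. Among Wnt pathway genes (0.33, adjusted p = 0.382) the ligand genes Wnt10a (2.66 ± 0.64) and Wnt7b (0.95), the receptor-degrading ligase gene Znrf3 (2.24 ± 0.49) and the cyclin gene Ccnd1 (1.13) rose, while Tbx3 (-1.71 ± 0.42) and the feedback gene Axin2 (-1.30 ± 0.46) fell. Among Hedgehog genes the ligand gene Ihh (1.14 ± 0.35) and the target gene Gli1 (0.93 ± 0.34) rose and the ligand-binding gene Hhip fell (-2.62 ± 0.77), and the fitted median of 0.62 and mean of -0.09 differed in sign (adjusted p = 0.670). Of the inflammatory signal list (0.24, adjusted p = 0.0511) the chemokine gene Ccl20 rose over all genes (1.92 ± 0.37, adjusted p = 0.0348), and Cxcl5 (3.05 ± 0.77), Lcn2 (2.25 ± 0.82), Tnfrsf12a (2.24 ± 0.50) and Ccl2 (1.30 ± 0.41) rose adjusted over the list alone. Ltb, a lymphotoxin gene of the lymphoid list, rose by that measure too (2.18 ± 0.59), while Ptprc, which encodes CD45, stood at -1.23 ± 1.37 (list -0.10, adjusted p = 0.670). The fetal liver list stood at -0.20 (adjusted p = 0.410, Afp 0.73 ± 0.80), the cell cycle list at 0.22 (adjusted p = 0.295, Mki67 0.50 ± 0.35), the Notch list at -0.64 (adjusted p = 0.137, Notch1 -0.90 ± 0.36) and the immediate early and stress list at 0.03 (adjusted p = 0.649, Fos 0.09 ± 0.36).

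At day 3 the comparison of 4 YFP-positive with 3 YFP-negative arrays asked for the difference early in injury. Krt19 averaged 2.01 (standard deviation 2.51) against -1.21 (2.42), a change of 3.23 ± 1.26 that did not pass (adjusted p = 0.600 over all genes, 0.0681 adjusted over the list alone). By limma 0 genes passed and 2089 had an unadjusted p under 0.05, while Ihh (1.96 ± 0.55) and Ccl20 (2.22 ± 0.59) rose adjusted over the list alone. The median of all genes was 0.15, or -0.42 with normexp. Biliary (2.26, 26 of 26 members positive) and epithelial junction genes (2.04, 13 of 14 positive) ran higher. Not every array followed its group, since the biliary and junction means were -1.46 and -2.43 on YFP-positive array 3 and -0.00382 and -1.15 on YFP-negative array 3. Stellate (-1.80), endothelial (-1.13, 19 of 19 negative), macrophage (-1.60, 20 of 20 negative), fetal liver (-1.08), erythroid (-1.76) and Notch genes (-0.81) ran lower. These 8 lists passed with the preset correlation, with adjusted p from 8.95e-11 to 0.0401, and none did otherwise (adjusted p = 0.383 to 0.559 with an estimated correlation). The macrophage difference rested on YFP-positive array 4, without which the fitted median was -0.14 and the list no longer passed. The stellate and endothelial means were also lowest on array 4 (-1.94 and 0.79), against 0.45 and 2.60 or higher on the other YFP-positive arrays. Part of these 2 differences thus rests on it, although both lists passed without it. Array 4 also had the highest biliary and epithelial junction means of all arrays (2.49 and 1.56). Calls also ended for fetal liver genes without YFP-negative array 3 (-0.87) and YFP-positive arrays 2 (-0.58) or 3 (-1.23), for erythroid genes without YFP-negative array 4 (-1.48) or YFP-positive array 2 (-1.28), and for Notch genes without YFP-negative array 3 (-0.52). With normexp the endothelial, macrophage, erythroid and Notch lists no longer passed. Without YFP-positive array 3 the gene count was 7 and without YFP-negative array 4 it was 1. With the slide as a fixed block the fitted medians were 2.13 for the biliary and -0.81 for the stellate list, the macrophage list turned to 1.40, the erythroid list turned in the camera test (fitted median -0.30), and the fetal liver list no longer passed (-1.0). That block also takes YFP-positive array 4 out, since no other array shared its slide.

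At day 7, with 3 arrays in each fraction, Krt19 stood at 3.81 ± 1.35 without passing. Adjusted over the list alone, the retinoid gene Lrat (-2.46 ± 0.71), the glutathione transferase genes Gsta1 (-2.26 ± 0.78) and Gstm1 (-1.67 ± 0.47), Ugdh (-1.97 ± 0.45) and Tbx3 (-2.28 ± 0.71) fell, and Gpx2 (2.26 ± 0.84) and Wnt10a (4.23 ± 1.09) rose. Ngfr also fell by that measure (-3.79 ± 1.05), but its other probe moved the opposite way. By limma 0 genes passed and 1405 had an unadjusted p under 0.05. Biliary (2.34, 26 of 26 positive), epithelial junction (2.0), cell cycle (0.31) and inflammatory signal genes (0.27) ran higher, and hepatocyte (-1.65, 23 of 24 negative), stellate (-2.10), erythroid (-3.00), oxidative stress and heme (-0.81) and lymphoid genes (-0.57) ran lower. All 9 passed with the preset correlation, with adjusted p from 1.84e-16 to 0.0169, and none did otherwise (adjusted p = 0.124 to 0.558 with an estimated correlation). The gene count was 4 and 1 without YFP-negative arrays 1 and 4 and 2, 3 and 2 without YFP-positive arrays 1, 3 and 4. Fitted medians with the slide as a fixed block were 2.14 for the biliary and -2.16 for the stellate list, while lymphoid (-0.41), erythroid (-2.01) and oxidative stress and heme genes (-0.72) no longer passed. Within slides 4 and 7 the sign differed for hepatocyte (-1.61 and 0.98), cell cycle (-0.46 and 1.23) and lymphoid genes (1.14 and -0.34). Single arrays ended the calls of lymphoid genes (-0.01 and -0.46 without YFP-negative arrays 3 and 4, 0.12 without YFP-positive array 1), cell cycle genes (0.42 and -0.07 without YFP-negative arrays 1 and 4, 0.05 without YFP-positive array 1), inflammatory genes (0.14 without YFP-negative array 1, 0.42 without YFP-positive array 3) and epithelial junction genes (1.30 without YFP-negative array 4).

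At day 14, with 2 YFP-positive and 3 YFP-negative arrays, Epha3, an ephrin receptor gene, was at least 248-fold lower in YFP-positive cells (adjusted p = 0.0463, chromosome 16, 63545155 to 63545214), with 1 of 2 other probes moving the opposite way. Rspo1, which encodes an enhancer of Wnt signalling (-7.29 ± 1.13, adjusted p = 0.0463), and the phospholipase gene Plcb1 (-3.47 ± 0.53, adjusted p = 0.0463) fell as well, without overlap of arrays, which the naming rule required. With p adjusted over the list alone, 11 stellate genes fell and 1 rose, with Col1a1 (-9.08 ± 1.87), Lum (-5.94 ± 1.58), Col3a1 (-5.78 ± 1.58) and Reln (-5.61 ± 1.27) first, and Hal fell too (-7.83 ± 2.01). Krt19 stood at 3.34 ± 1.51. In all 6 genes passed, 0 of them higher, 3 with identifiers only, and the median of all genes was 0.13, or 0.49 with normexp. Biliary (2.80, 26 of 26 positive) and epithelial junction genes (2.54, 14 of 14 positive) ran higher, and stellate (-2.99), endothelial (-1.03, 19 of 19 negative) and neutrophil genes (-1.83) ran lower. These 5 lists passed with the preset correlation, with adjusted p from 3.34e-12 to 0.0310, and none did otherwise (adjusted p = 0.220 to 0.779 with an estimated correlation). The count was 0, 2 and 0 without YFP-negative arrays 1, 2 and 3, 24 and 44 without YFP-positive arrays 1 and 2, and 0 with normexp and with quantile normalization. No slide held both fractions at this day, so a fit with the slide as a fixed block rests on slide differences estimated from other groups. With it the fitted medians were 2.51 for the biliary and -2.24 for the stellate list, while the neutrophil list turned to 0.96. Its call also ended without YFP-negative array 3 (-1.42) and without YFP-positive array 1 (-1.57), and that of endothelial genes without YFP-positive array 2 (-0.35).

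The next 6 comparisons set each sorted fraction against day 0 and asked how the sorted cells of fed mice differ from the chow-fed preparation. All 6 share the same 2 day 0 arrays, and diet, sort and gate changed together, so none of them isolates the diet. The median of all genes lay between -0.42 and -0.20 in them, and values of single genes are given as fitted. With the slide as a fixed block 2, 0 and 0 genes passed for YFP-negative and 7, 0 and 21 for YFP-positive cells at days 3, 7 and 14. Array weights gave 69, 88, 514, 93, 859 and 131 in the same order. A fit of only the groups compared gave 0 in each. Of the lists, the fixed block lowered the fitted biliary medians of YFP-positive cells to 0.27, 0.30 and 0.84 at days 3, 7 and 14, and the list no longer passed at day 7. In YFP-negative cells it ended the calls of the macrophage and neutrophil lists at days 3 and 7, of the hepatocyte list at day 3 and of the stellate list at day 7.

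**Figure D3:**
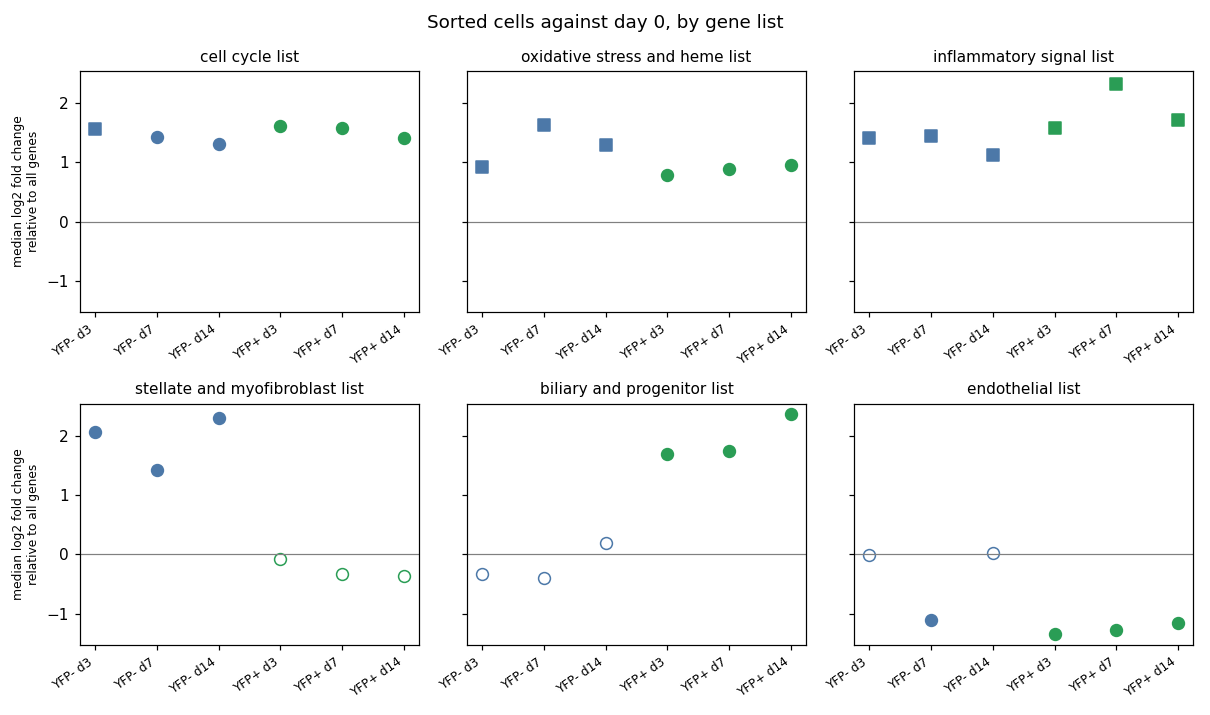
Median log2 fold change of 6 gene lists against day 0, relative to all genes, for YFP-negative (blue) and YFP-positive cells (green) at 3 days; filled markers passed with the preset correlation and squares also with an estimated one. The inflammatory list lay between 1.12 and 2.33.

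In YFP-negative cells at day 3 (3 arrays), Steap1, a metalloreductase family gene (5.14 ± 0.82, adjusted p = 0.0360), the urokinase receptor gene Plaur (3.58 ± 0.58, adjusted p = 0.0360) and Tubb6 (2.97 ± 0.42, adjusted p = 0.0173), a tubulin gene whose other probe moved the opposite way, rose. Among the 9 falls were the thyrotropin-releasing hormone receptor gene Trhr (at least 45.9-fold lower, adjusted p = 7.66e-05), the cone opsin gene Opn1mw (at least 14.2-fold, adjusted p = 0.000367) and the olfactory receptor genes Olfr39 (at least 11.9-fold, adjusted p = 0.0173) and Olfr1324 (at least 9.08-fold, adjusted p = 0.0320). With normexp Opn1mw, Olfr39 and Olfr1324 turned, to 0.27, 0.24 and 0.39. Among list members adjusted over the list alone, 4 cell cycle genes rose, namely the mitotic kinase gene Aurkb (at least 32.5-fold), Tk1 (3.26 ± 0.82), Top2a (2.34 ± 0.72, with 1 of 2 other probes opposite) and Birc5 (2.11 ± 0.61), and so did Gsta1 (3.43 ± 0.87) and Myc (1.93 ± 0.51). In all 12 genes passed, 3 higher, 5 with identifiers only. The split was 3 of 6 with quantile normalization, and with normexp no gene passed.

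The cell cycle list (1.57, 27 of 30 positive, adjusted p = 9.60e-19), the oxidative stress and heme list (0.91, adjusted p = 3.79e-05) and the inflammatory signal list (1.41, adjusted p = 2.14e-05) were higher, each also with adjusted p = 0.0357 with an estimated correlation. Neutrophil (3.08), macrophage (2.53), stellate (2.06), lymphoid (1.18) and hepatocyte genes (0.76) passed only with the preset correlation (adjusted p = 0.117 to 0.675 with an estimated correlation). The number of genes was 4 and 30 without day 0 arrays 1 and 2, and 5, 5 and 3 without YFP-negative arrays 1, 3 and 4. With the slide as a fixed block the fitted medians were 1.09 for the cell cycle, 0.60 for the oxidative stress and heme and 0.36 for the inflammatory list, which no longer passed, and lymphoid genes turned to -0.47. On slide 1 the 3 lists stood at 1.19, 0.68 and 0.66. Without day 0 array 2 the lymphoid (-0.10 as fitted) and neutrophil lists (0.91) no longer passed, nor did the hepatocyte (-0.26) and lymphoid lists (-0.04) without YFP-negative array 4. With normexp the hepatocyte (0.38) and lymphoid lists (0.97) no longer passed, and with the macrophage list as a covariate the hepatocyte (-0.19), lymphoid (-0.39) and neutrophil lists (0.48) did not.

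In YFP-negative cells at day 7 (3 arrays), the glutathione transferase genes Gsta2 (9.33 ± 1.40, adjusted p = 0.0230) and Gsta1 (5.47 ± 0.87, adjusted p = 0.0339), the apolipoprotein gene Apoc2 (4.55 ± 0.68, adjusted p = 0.0230), Plaur (4.18 ± 0.58, adjusted p = 0.0136) and Tubb6 (3.19 ± 0.42, adjusted p = 0.0136) rose. Olfr869 (at least 17.3-fold, adjusted p = 0.0286), Opn1mw (at least 9.03-fold, adjusted p = 0.00350), Trhr (-3.72 ± 0.53, adjusted p = 0.0165) and Olfr1324 (at least 6.42-fold, adjusted p = 0.0339) were lower. Adjusted over the list alone, the neutrophil chemokine genes Cxcl5 (4.96 ± 1.46) and Cxcl2 (4.84 ± 1.16), Ccl2 (3.11 ± 0.78), Lrat (3.37 ± 0.80), Gstm1 (2.29 ± 0.52), Srxn1 (1.78 ± 0.65) and Ugdh (1.75 ± 0.50) rose. So did Kif20a (2.43 ± 0.75), Aurkb (at least 21.0-fold) and Myc (1.92 ± 0.51), while the Notch ligand gene Dll4 fell (-2.39 ± 0.66). In all 13 genes passed, 6 higher, 3 with identifiers only. The split was 8 of 11 with quantile normalization and 5 of 5 with normexp.

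Oxidative stress and heme genes (1.62, adjusted p = 5.30e-08, and 0.0104 with an estimated correlation) and inflammatory signal genes (1.44, adjusted p = 2.78e-06, and 0.0135 with an estimated correlation) were higher. Neutrophil (4.15), hepatocyte (2.15), macrophage (1.76), cell cycle (1.42), stellate (1.41) and lymphoid genes (1.41) ran higher and endothelial genes (-1.10) lower with the preset correlation only (adjusted p = 0.148 to 0.483 with an estimated correlation). The gene count was 0 and 30 without day 0 arrays 1 and 2, and 37 and 2 without YFP-negative arrays 1 and 3. No slide held both groups. Fitted medians with the slide as a fixed block were 1.15 for the oxidative and 0.96 for the inflammatory list, which no longer passed, and the lymphoid list turned to -0.12. Without day 0 array 2 the macrophage (0.34 as fitted) and lymphoid lists (0.18) no longer passed, nor did the stellate list without YFP-negative array 1 (0.36) and the lymphoid list without array 3 (0.25). The macrophage covariate ended the lymphoid call (0.23).

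In YFP-negative cells at day 14 (3 arrays), Plaur (3.64 ± 0.58, adjusted p = 0.0397) and Lrg1, an acute phase glycoprotein gene (2.95 ± 0.42, adjusted p = 0.0157), rose. Trhr (at least 43.3-fold, adjusted p = 6.06e-05), Opn1mw (at least 13.4-fold, adjusted p = 0.000345) and Olfr1324 (at least 8.74-fold, adjusted p = 0.0122) were lower. With p adjusted over the list alone, Cxcl5 (6.01 ± 1.46), Lrat (4.32 ± 0.80), Gsta1 (3.72 ± 0.87), Ccl2 (2.59 ± 0.78), Myc (2.12 ± 0.51), Nqo1 (1.62 ± 0.59), Gstm1 (1.47 ± 0.52), the thioredoxin reductase gene Txnrd1 (0.88 ± 0.31) and Aurkb (at least 23.8-fold) rose. In all 9 genes passed, 2 higher, 4 with identifiers only. The split was 4 of 7 with quantile normalization, and with normexp no gene passed. Oxidative stress and heme genes (1.30, adjusted p = 1.68e-07, and 0.0129 with an estimated correlation) and inflammatory signal genes (1.12, adjusted p = 6.68e-06, and 0.0176 with an estimated correlation) were higher. Stellate (2.30), hepatocyte (1.79), neutrophil (1.72), cell cycle (1.31) and immediate early genes (0.71) ran higher and lymphoid genes (-1.17) lower with the preset correlation only (adjusted p = 0.104 to 0.788 with an estimated correlation). The number of genes was 4 and 55 without day 0 arrays 1 and 2 and 5 without YFP-negative array 1. No slide held both groups. With the slide as a fixed block the fitted medians were 0.73 for the oxidative and 0.43 for the inflammatory list, which no longer passed, the neutrophil list turned to -2.00, and the immediate early list no longer passed (-0.12). Calls also ended for lymphoid genes without day 0 array 1 (-0.94 as fitted), for neutrophil genes without day 0 array 2 (-0.17) or YFP-negative array 3 (0.85), and for immediate early genes without day 0 arrays 1 (0.21) or 2 (0.27) or YFP-negative array 3 (-0.09).

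In YFP-positive cells at day 3 (4 arrays), the interleukin 1 receptor antagonist gene Il1rn (6.57 ± 1.0, adjusted p = 0.0253), the replication licensing gene Dtl (6.26 ± 0.98, adjusted p = 0.0269, with both of its 2 other probes opposite), the epithelial stress gene Sprr1a (5.24 ± 0.85, adjusted p = 0.0326), Steap1 (4.95 ± 0.78, adjusted p = 0.0269) and Plaur (3.90 ± 0.55, adjusted p = 0.0138) rose. Trhr (at least 31.7-fold, adjusted p = 5.79e-05), Opn1mw (at least 9.81-fold), Olfr39 (at least 8.26-fold) and the meiotic methyltransferase gene Prdm9 (-4.38 ± 0.69, adjusted p = 0.0269) were lower. Among list members adjusted over the list alone, Cxcl5 (7.03 ± 1.38), Lcn2 (5.83 ± 1.48), Ccl2 (3.01 ± 0.74), the adhesion gene Vcam1 (1.56 ± 0.38), the keratin gene Krt8 (3.15 ± 0.82), Gsta1 (3.48 ± 0.83) and 10 cell cycle genes rose. Aurkb (at least 15.7-fold), Top2a (2.97 ± 0.69) and Rrm2 (2.89 ± 0.97) were among the latter, and the glypican gene Gpc3 fell (-2.95 ± 0.73). In all 14 genes passed, 6 higher, 4 with identifiers only, and with normexp the split was 2 of 2.

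Inflammatory signal genes were higher by 1.58 (adjusted p = 2.51e-06, and 0.0225 with an estimated correlation). Neutrophil (2.23), epithelial junction (1.76), biliary (1.70), cell cycle (1.61), oxidative stress and heme (0.79), hepatocyte (0.56) and lymphoid genes (0.46) ran higher and endothelial genes (-1.34) lower with the preset correlation only (adjusted p = 0.0861 to 0.641 with an estimated correlation). The gene count was 4 and 33 without day 0 arrays 1 and 2, and 6, 8 and 65 without YFP-positive arrays 1, 2 and 3. The fitted inflammatory median was 1.1 with the slide as a fixed block, and on slides 1 and 3 the list stood at 1.97 and 0.98. The biliary list stood at 2.01 on slide 1 and at no difference on slide 3, which held array 3. The endothelial (-0.43 as fitted) and epithelial junction lists (0.41) no longer passed with that block. Single arrays ended the calls of neutrophil (0.45 without day 0 array 2, 1.07 and 1.65 without YFP-positive arrays 1 and 3), lymphoid (-0.17, 0.01 and 0.22 without the same arrays) and hepatocyte genes (0.07 without day 0 array 1, -0.38 without YFP-positive array 1). The macrophage covariate ended the last 2 as well (0.21 and 0.14).

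In YFP-positive cells at day 7 (3 arrays), Il1rn (6.99 ± 1.05, adjusted p = 0.0257), Steap1 (5.26 ± 0.82, adjusted p = 0.0343), Plaur (4.50 ± 0.58, adjusted p = 0.00683) and Tubb6 (3.13 ± 0.42, adjusted p = 0.0109) rose. Trhr (at least 25.7-fold, adjusted p = 0.000267), Opn1mw (at least 8.11-fold, adjusted p = 0.00132) and Olfr1324 (at least 5.29-fold, adjusted p = 0.0343) were lower. Adjusted over the list alone, Cxcl5 (8.27 ± 1.46), Lcn2 (5.46 ± 1.56), Cxcl2 (4.74 ± 1.16), Ccl2 (4.26 ± 0.78), Myc (2.72 ± 0.51) and 13 cell cycle genes rose, Aurkb (at least 45.6-fold) and the cyclin gene Ccnb1 (3.14 ± 1.12) among them. Alas2 (-6.85 ± 2.46), Hbb-b1 (-5.98 ± 2.01), Hba-a1 (-5.52 ± 1.68) and Dll4 (-2.62 ± 0.66) fell. In all 9 genes passed, 4 higher, 2 with identifiers only, while the split was 30 of 36 with quantile normalization and 2 of 2 with normexp. Inflammatory signal genes were higher by 2.33 (adjusted p = 4.60e-09, and 0.00411 with an estimated correlation). Neutrophil (3.96), macrophage (2.05), epithelial junction (1.97), biliary (1.75), cell cycle (1.57), immediate early (1.01) and oxidative stress and heme genes (0.89) ran higher, and erythroid (-3.88), endothelial (-1.27) and Notch genes (-0.84) lower, with the preset correlation only (adjusted p = 0.0876 to 0.568 with an estimated correlation). The number of genes was 1 and 40 without day 0 arrays 1 and 2 and 4 without YFP-positive array 4. No slide held both groups, and the fitted inflammatory median was 1.1 with the slide as a fixed block. With that block the biliary (0.30), macrophage (0.63), epithelial junction (-0.18), immediate early (-0.40) and erythroid lists (-3.78) no longer passed. Calls also ended for macrophage (0.46 as fitted), epithelial junction (0.98) and oxidative stress and heme genes (0.43) without day 0 array 2, and for erythroid genes (-1.41) without day 0 array 1. So did those of immediate early genes without day 0 array 1 (0.35) or YFP-positive array 3 (0.20), and of Notch genes without day 0 arrays 1 and 2 (-1.24 and -1.33) or YFP-positive arrays 3 and 4 (-1.17 and -0.79).

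In YFP-positive cells at day 14 (2 arrays), Cxcl5 (8.69 ± 1.60, adjusted p = 0.0477, chromosome 5, 91190205 to 91190264), Il1rn (6.87 ± 1.15, adjusted p = 0.0237), Steap1 (5.60 ± 0.90, adjusted p = 0.0205), Apoc2 (4.11 ± 0.75, adjusted p = 0.0464) and Plaur (adjusted p = 0.0166) rose. Akap6, a gene of muscle and nerve (at least 156-fold, adjusted p = 0.0477), Fam65b, now Ripor2 (at least 80.3-fold, adjusted p = 0.0166), the testis gene Spata9 (-6.42 ± 0.94, adjusted p = 0.0166), the interferon-induced gene Oas1g (-6.27 ± 1.08, adjusted p = 0.0299) and Trhr (at least 28.4-fold, adjusted p = 0.000487) were lower. With p adjusted over the list alone, Lcn2 (6.13 ± 1.71), Wnt10a (5.34 ± 1.34), Ccl2 (4.57 ± 0.86) and Cxcl2 (3.65 ± 1.27) rose, and Tagln (-3.06 ± 0.86) and Col1a1 (-7.07 ± 2.05, with 1 of 2 other probes opposite) fell. In all 38 genes passed, 11 higher, 17 with identifiers only, while the split was 29 of 56 with quantile normalization and no gene passed with normexp. Inflammatory signal genes were higher by 1.71 (adjusted p = 5.49e-07, and 0.0147 with an estimated correlation). Epithelial junction (2.94), biliary (2.36, 26 of 26 positive), cell cycle (1.41), oxidative stress and heme (0.95), hepatocyte (0.92) and immediate early genes (0.53) ran higher and endothelial genes (-1.15) lower with the preset correlation only (adjusted p = 0.118 to 0.684 with an estimated correlation). The gene count was 2 and 20 without day 0 arrays 1 and 2 and 17 and 67 without YFP-positive arrays 1 and 2. The fitted inflammatory median was 1.37 with the slide as a fixed block, and on slide 1 the list stood at 2.39. Immediate early genes no longer passed with that block (0.33 as fitted), without day 0 array 1 (0.38) or without YFP-positive array 2 (0.17), nor did hepatocyte genes without YFP-positive array 1 (0.29) and endothelial genes without array 2 (-0.63). With normexp the immediate early list did not pass either (0.30).

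The authors' deposited table holds these 6 comparisons as signed fold changes with a false discovery rate. In the authors' deposited table Steap1 stood at 22.5-fold for YFP-negative and 20.8-fold for YFP-positive cells at day 3, with false discovery rates of 1.49 and 3.04 percent. Each rise named above by its adjusted p over all genes was under 5 percent in the authors' deposited table, but only 1 of the falls so named was at day 7 (Trhr, 4.36 percent) and 3 at day 14 (Spata9, Oas1g and Trhr), all in YFP-positive cells. For YFP-negative cells at day 3 the authors' deposited table gave Trhr at -18.5-fold (12.8 percent), Opn1mw at -3.26-fold (22.8 percent), Olfr39 at -3.08-fold (19.8 percent) and Olfr1324 at -2.35-fold (26.1 percent), all smaller than the bounds printed here. These bounds are therefore not lower limits of the true change. Of the 42175 probes of the authors' deposited table, 1423, 1527 and 690 had a false discovery rate under 5 percent for YFP-negative cells at days 3, 7 and 14, and 818, 4476 and 6880 for YFP-positive cells. Of these probes 1382, 1303 and 645 were higher and 41, 224 and 45 lower for YFP-negative cells in the authors' deposited table, and 645, 2224 and 3686 higher and 173, 2252 and 3194 lower for YFP-positive cells. The larger number of falls than of rises here thus did not recur in the authors' deposited table, except for YFP-positive cells at day 7. Matched to the genes tested here, the probes under that rate were 924, 918 and 376 genes and 517, 2727 and 4188 genes in the authors' deposited table, against 12, 13, 9, 14, 9 and 38 here. Method and number of samples may both differ, and the gap was not traced to either. At least 98.9 percent of the matched genes under that rate in the authors' deposited table had the same direction here. The 2 sources come from 1 series and are not independent.

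The comparison of day 14 with day 3 within each fraction asked what changes as injury goes on. In YFP-negative cells (3 and 3 arrays) the T and natural killer cell genes Gzmb (-6.01 ± 1.85), Cd8a (-4.05 ± 1.29), Cd2 (-4.01 ± 1.26) and Klrk1 (-3.75 ± 1.26) fell and Gpc3 (2.32 ± 0.68) rose, all adjusted over the list alone. A CD45-negative sort should hold few cells with such immune genes, and Ptprc averaged 2.19 at day 3 and -0.63 at day 14. Falls of immune genes may therefore lie in leukocytes left by each sort, which was not tested. By limma 0 genes passed over all genes and 985 had an unadjusted p under 0.05, and 2 passed without YFP-negative day 14 array 2. Macrophage (-2.73, 20 of 20 negative), lymphoid (-2.60) and cell cycle genes (-0.38) ran lower and hepatocyte (0.89), biliary (0.55) and oxidative stress and heme genes (0.31) higher, with adjusted p from 6.90e-13 to 0.0365 (adjusted p = 0.373 to 0.616 with an estimated correlation). The fitted macrophage median was -2.92 with the slide as a fixed block, and on slides 6 and 7 the list stood at -3.79 and -1.85. On the same slides the sign differed for hepatocyte (2.97 and -1.68), biliary (-1.25 and 1.84), oxidative stress and heme (1.35 and -0.93) and cell cycle genes (0.49 and -0.90). With normexp the median of all genes was -0.59, and the cell cycle list turned relative to it (fitted median -0.54). Biliary (0.42), cell cycle (-0.20) and oxidative lists (0.34) no longer passed with the slide as a fixed block. Single arrays ended the calls of biliary genes (-0.11 without day 3 array 1, where the test turned, and -0.11 without day 14 array 3), of hepatocyte genes (0.76 and 0.35 without day 3 arrays 1 and 3, 0.49 and 0.45 without day 14 arrays 1 and 2), of oxidative stress and heme genes (0.26, 0.05, 0.08 and 0.22 without the same arrays) and of cell cycle genes (-0.30 without day 3 array 3, -0.24 and -0.09 without day 14 arrays 1 and 3). With the macrophage list as a covariate the biliary call ended (-0.32).

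In YFP-positive cells (2 and 4 arrays) Fam65b, now Ripor2, was at least 113-fold lower at day 14 (adjusted p = 0.00903), and Ifi27, now Ifi27l2a, an interferon-induced gene (-6.67 ± 1.03, adjusted p = 0.0389), and Plcb1 (-3.94 ± 0.50, adjusted p = 0.00903) fell. Wnt10a (5.84 ± 1.16), the Wnt receptor ligase gene Rnf43 (4.14 ± 1.07) and Gpc3 (2.96 ± 0.73) rose adjusted over the list alone. In all 7 genes passed, 0 of them higher, 4 with identifiers only. Neutrophil (-2.76, 12 of 12 negative), lymphoid (-1.34), macrophage (-1.32) and stellate genes (-0.48) ran lower, and epithelial junction (0.86), biliary (0.84), immediate early (0.45) and Wnt genes (0.40) higher, with the preset correlation only (adjusted p = 0.309 to 0.588 with an estimated correlation). The same limit holds for the immune lists here, with Ptprc at a mean of -0.04 at day 3 and -1.80 at day 14. The count was 11 and 35 without day 3 arrays 3 and 4 and 21 and 42 without day 14 arrays 1 and 2. The fitted macrophage median was -3.35 with the slide as a fixed block, and on slides 1 and 2 the list stood at -4.43 and -1.86. Day 3 array 4 had a macrophage mean of -2.81, against 2.49 or higher on the other day 3 arrays, which makes the macrophage fall smaller. All 8 lists passed without that array. It was alone on its slide, so the fixed block takes it out. Of the 8 lists 0 passed without day 14 array 1, 1 without day 3 array 3, 1 with the macrophage list as a covariate (Wnt genes, 0.72) and 5 with normexp, which ended the biliary (0.65), epithelial junction (0.70) and immediate early calls (0.40). Fitted medians without day 14 array 1 were -2.06 for neutrophil, -0.96 for lymphoid, -0.83 for macrophage, -0.23 for stellate, 0.83 for biliary, 1.13 for epithelial junction, 0.67 for immediate early and 1.09 for Wnt genes. Without day 3 array 3 they were -2.64 for neutrophil, -1.01 for macrophage, -0.37 for stellate, 0.15 for biliary, -0.08 for epithelial junction, 0.27 for immediate early and 0.07 for Wnt genes, and only the lymphoid list passed. Day 3 array 1 ended the neutrophil (-1.80), macrophage (-0.82), lymphoid (-0.83), stellate (-0.23) and immediate early calls (0.22), day 3 array 2 the stellate (-0.43), epithelial junction (0.93) and immediate early calls (0.43), and day 14 array 2 the epithelial junction (0.28), Wnt (-0.24) and immediate early calls (0.21). The epithelial junction (0.67) and Wnt lists (0.29) no longer passed with the slide as a fixed block.

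The difference of these differences asked whether YFP-positive and YFP-negative cells moved apart between days 3 and 14. Stellate genes did so as a list (-0.88, or -0.85 as fitted, adjusted p = 0.00128, and adjusted p = 0.870 with an estimated correlation), and none of the other 16 lists passed. The call ended without YFP-positive day 14 array 1 (-0.45 as fitted) and without YFP-negative day 3 array 1 (-0.77). Other lists passed beside the stellate list under some alternatives. In all 4 lists passed with normexp, 4 without YFP-negative day 14 array 2 and 4 without YFP-positive day 3 array 1. By limma 0 genes passed and 760 had an unadjusted p under 0.05, while 1 passed with normexp, 1 without YFP-negative day 14 array 2 and 1 without YFP-positive day 3 array 4.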

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

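Tests of the first paragraph were set in advance, apart from the removal of 2 arrays together, and every test of the 3 patterns below was chosen only after the result was seen, although the prediction for the first test of genomic DNA was written before its value was known.

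Among 21 measures tested in the only group of 4 arrays, YFP-positive day 3 array 4 stood apart from the other 3 in the stellate list (Dixon ratio 0.884), the Hedgehog list (0.849) and the 75th percentile of the signal (0.899), all above the critical value for 4 arrays, which chance passes about 1 time in 20. Of all 20 arrays it also had the highest biliary mean (2.49), epithelial junction mean (1.56) and Krt19 signal (4.48). Its Ptprc signal was the lowest (-7.55). Whether it differs in cell content or in quality was not tested. The stellate list also differed between the fractions at day 14 against day 3 (-0.85), with the preset correlation but not with an estimated one. Without YFP-positive day 3 arrays 3 and 4 that difference was -1.60, but its call ended without YFP-positive day 14 array 1 (-0.45) and without YFP-negative day 3 array 1 (-0.77).

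YFP-positive day 3 array 3 resembled YFP-negative arrays: its biliary list mean was -1.46, while the other 3 arrays of its group lay at 1.07 or higher. Low signal is argued against, with 87.7 percent of its spots well above background against 81.0 to 85.4 percent on the other 3. A single wrong label or a sort that held YFP-negative cells stays open, because across 26361 genes outside the lists, which are not independent, its mean r with YFP-negative day 3 arrays exceeded that with its own group by 0.0759 (0.942 against 0.866), but by 0.0360 without array 4, under the 0.05 set for the test. The same gap was 0.0155 and 0.0227 for YFP-positive day 3 arrays 1 and 2 and -0.0329 for array 4. An exchange with YFP-negative day 3 array 3 stays open as well, and both readings were changed to open after values were seen, the first from supported and the second from excluded. The biliary mean of that array (-0.00382) lay below the lowest YFP-positive one of any day (0.21) by less than the spread, and its Krt19 was 1.46 against -1.87 or lower on the other YFP-negative day 3 arrays, while its stellate mean of 2.17 (YFP-positive arrays 0.76 or lower) goes against it, and its mean r of 0.911 with YFP-negative and 0.846 with the other YFP-positive day 3 arrays (0.881 without array 4) does so less clearly.

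Immune genes varied between arrays although the cells were sorted as CD45-negative, which should take leukocytes away. Ptprc, which encodes CD45, averaged 2.19 and 2.66 on YFP-negative arrays at days 3 and 7, against -0.18 on day 0 arrays. On YFP-positive arrays it averaged -0.04 at day 3 and 2.36 at day 7. At day 14 it averaged -0.63 on YFP-negative and -1.80 on YFP-positive arrays. The sort thus did not keep CD45 mRNA out of every sorted group. Deviations from group means of the neutrophil list followed those of the macrophage list over 18 arrays (r 0.881, permutation p 2e-05; rho 0.860, permutation p 8e-05; adjusted over 16 relations 0.000240 and 0.000640; r 0.871 without the 2 farthest), and so did those of the lymphoid list (r 0.811 and rho 0.839, permutation p 3e-05 each, adjusted 0.000240 and 0.000480; r 0.796 without the 2 farthest). Leukocytes left in the sorted cells may be the source. A lower share of the main cell types stays open (endothelial r 0.287, and -0.0384 without the 2 farthest; stellate r 0.456), and so does the slide, which held 54.3 percent of the within-group variance (permutation p 0.473), a reading loosened to open after that value was seen. The biological explanation, leukocyte genes active in the traced cells, was not tested because the arrays hold mixed RNA. As the sole source it is argued against at days 3 and 7, since untraced cells carried macrophage genes too. The list ran from 3.03 to 3.52 and from -0.09 to 4.11 on YFP-negative arrays at these days. On YFP-positive arrays it ran from -2.81 to 3.67 and from 0.87 to 3.82.

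Olfactory receptor genes (845 measured) were lower on sorted arrays than on day 0 arrays by -0.30 to -1.20 relative to all genes. Background correction of dim spots stays open as a source, since with normexp the comparisons ran from -0.43 to 0.21. The most negative value met the rule set against this correction as the sole source. That rule rests on the lowest comparison alone, without a measure of spread, so it cannot decide. Genomic DNA in the day 0 RNA stays open: among the dimmest 25 percent of probes, one-exon probes exceeded junction probes by 0.136 (0.0821 to 0.197), which met the prediction written beforehand, but the gap was 0.187 among the brightest 25 percent, and the rule was tightened after that was seen. As the whole cause it is argued against, because junction probes, which genomic DNA should not raise, showed a dim-minus-bright excess of 0.973, against 0.921 for one-exon probes. No biological explanation was tested, since diet, sort and gate changed together, and the falls of Trhr, Opn1mw and the olfactory genes may therefore be technical.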

How the results depend on the processing

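The alternatives added after results were seen were the removal of YFP-positive day 3 arrays 3 and 4, days 7 and 14 alone, the macrophage covariate and junction probes only. For every change below the cause was not tested. With an estimated correlation 10 of 99 list calls passed, and with the slide as a fixed block 61 stayed, 28 ended and 10 turned. The fixed block takes out YFP-positive day 3 array 4, which was alone on its slide, and leaves fewer residual degrees of freedom. Changes under it are therefore not those of the slide alone. Leaving out that array by itself turned 0 of 35 list calls, so its loss alone does not account for the turns. The share of spots well above background was 89.9 and 91.2 percent on the day 0 arrays and 81.0 to 88.3 percent on the sorted arrays, so falls of dim genes against day 0 run the same way as this difference, and its part in them stays open. An analysis of the authors' own per-sample values was not run, because their table holds comparisons only. Where 1 array is left in a group, it is assumed to vary like the others.

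With normexp the counts were 0 at day 14 and 43 over the mean of days for YFP-positive against YFP-negative cells, 0, 5 and 0 for YFP-negative and 2, 2 and 0 for YFP-positive cells against day 0 at days 3, 7 and 14, 1 for YFP-positive cells at day 14 against day 3, and 1 for the difference. The cell cycle list of YFP-negative cells at day 14 against day 3 turned in the direction of the camera test only (fitted median -0.54). The values of Olfr39 (0.24), Opn1mw (0.27) and Olfr1324 (0.39) turned in YFP-negative cells at day 3. Quantile normalization gave 0 at day 14, 1107 over the mean of days, 6 for YFP-negative cells at day 3 and 36 for YFP-positive cells at day 7 against day 0. A filter on the share of arrays gave 0, 4 and 0 for YFP-negative and 6 and 2 for YFP-positive cells (days 3 and 7) against day 0. The mean of the probes gave 1 at day 14, 9 and 5 for YFP-positive cells at days 3 and 7 against day 0 and 3 for day 14 against day 3, and Acta2 turned to -1.70.

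The slide as a random block (correlation 0.0966) gave 1 at day 14. It ended the list calls of neutrophil genes at day 14 (fitted median -1.66), of hepatocyte (-0.71), macrophage (-0.61) and neutrophil genes (-0.83) over the mean of days, and of immediate early genes of YFP-negative cells at day 14 against day 0 (0.24). As a fixed block it gave 2 over the mean of days, 2, 0 and 0 for YFP-negative and 7, 0 and 21 for YFP-positive cells against day 0, and 15 for YFP-positive cells at day 14 against day 3. Lists that turned under it, with fitted medians, were lymphoid for YFP-negative cells at day 3 (-0.47) and day 7 (-0.12), neutrophil for YFP-negative cells at day 14 (-2.00), at day 14 between the fractions (0.96) and over the mean of days (1.91), and macrophage at day 3 (1.40) and over the mean of days (1.07). Erythroid at day 3 (-0.30) and over the mean of days (-1.12) and hepatocyte over the mean of days (-0.13) kept the sign of the median and turned only in the direction of the camera test. Emr1 (1.1), Ptprc (1.70) and S100a8 (1.74) turned over the mean of days. Whether the replicate numbers pair the samples stays open. The profile with the same number was the closest for 2 of 8 samples, with correlations from -0.239 to 0.391. These are correlations of deviations from the means of small groups. At day 14 the deviations of the 2 YFP-positive arrays mirror each other, so they cannot show an absence of pairing. As a block the replicate numbers gave 1 at day 14, 42 over the mean of days, 3, 0 and 4 for YFP-negative and 3, 3 and 20 for YFP-positive cells against day 0, and 3 for YFP-positive cells at day 14 against day 3.

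A trended, robust variance gave 322 over the mean of days and 24 and 61 for YFP-positive cells at days 7 and 14 against day 0. Array weights gave 29 at day 14, 69, 88 and 514 for YFP-negative and 93, 859 and 131 for YFP-positive cells against day 0 and 1 for YFP-negative cells at day 14 against day 3, and Alb turned to -0.18. A fit of only the groups compared gave 68 over the mean of days, 0, 0 and 0 for each fraction against day 0 and 0 for YFP-positive cells at day 14 against day 3. No filter and a minimum of 2-fold moved no count by more than 1.5 times.

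Without YFP-positive day 3 arrays 3 and 4 the counts were 1 at day 3, 758 over the mean of days, 33 for YFP-positive cells at day 3 against day 0 and 34 at day 14 against day 3, and Alb (-0.00301) and Fos (-0.0634) turned. With days 7 and 14 alone 17 passed and Alb turned to -0.12. The macrophage covariate gave 13 at day 14, 23 and 23 for YFP-negative and 15 and 64 for YFP-positive cells at days 7 and 14 against day 0, and Alb (-0.0588), Fos (-0.0181) and Emr1 (0.11) turned, as did the macrophage list of YFP-negative cells at day 14 against day 3 in the camera test only (fitted median -0.18). Junction probes only (3015 genes) gave 2, 3 and 2 for YFP-negative and 4, 2 and 4 for YFP-positive cells against day 0, and the hepatocyte list of YFP-positive cells at day 14 turned (fitted median -0.85). Of the 99 list calls normexp ended 13 and turned 1, quantile normalization ended 11, the replicate block 15, and the macrophage covariate ended 20 and turned 1, among them calls of the macrophage list itself, which such a fit removes by design. The filter on the share of arrays ended 2, the mean of the probes 1, leaving out YFP-positive day 3 arrays 3 and 4 together 8 of 35, and days 7 and 14 alone 1 of 9. With junction probes only 30 of 46 list calls ended and 1 turned.

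Leaving out 1 array at a time gave 0 to 7, 0 to 4 and 0 to 44 for YFP-positive against YFP-negative cells at days 3, 7 and 14 and 16 to 1219 over the mean of days. It gave 3 to 30, 0 to 37 and 4 to 55 for YFP-negative and 4 to 65, 1 to 40 and 2 to 67 for YFP-positive cells against day 0. Day 14 against day 3 gave 0 to 2 for YFP-negative and 5 to 42 for YFP-positive cells, and the difference 0 to 1. Alb ranged from -0.10 to 0.19, Fos from -0.0742 to 0.22 and the biliary list of YFP-negative cells at day 14 against day 3 from -0.11 to 1.11.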

Other observations

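The cilium test and its repeats under other settings were chosen only after the rise of Foxj1 and Dnali1 was seen, while the regroupings of arrays were planned.

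A list of 50 motile cilium genes was written before its test, and 44 were measured. Over the mean of days 39 of them were higher in YFP-positive cells, with a median of 0.86 relative to all genes. Dnahc5, an outer arm dynein heavy chain gene (3.04 ± 0.73), and Capsl (2.57 ± 0.70) were among 7 members that rose adjusted over the list alone, and Ccdc114 (2.35 ± 0.50) rose over all genes, 1 member in all.

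The camera test of that list gave p = 6.59e-07 with the preset correlation by limma, and p = 0.0405 with an estimated one. With normexp the latter was 0.150 and with the slide as a fixed block 0.0851 (relative median 0.30), while it was 0.0344 with quantile normalization and 0.0256 and 0.0346 without YFP-positive day 3 arrays 3 and 4. By day it was 0.110, 0.217 and 0.0412. A motile cilium programme in part of the traced cells is a hypothesis that may be tested by microscopy, and these arrays leave it open.

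Regrouping the arrays tested whether the number of genes over the mean of days can come by chance. The real split gave 171 genes, the highest of the other splits 5, and 1 of 100 splits, the real one, reached 171. Only 100 of the possible splits were drawn, and those not drawn may reach that count. Chance is thus less likely for it but not excluded. The splits did not take slides into account, and with the slide as a fixed block 2 genes passed. At day 3 the real split gave 0 genes and all 35 splits reached that, as any split must, so this share tests nothing. The highest other split gave 169, with YFP-negative array 3 and YFP-positive arrays 1, 2 and 4 on one side and YFP-negative arrays 1 and 4 and YFP-positive array 3 on the other. That split is the real one with YFP-positive array 3 and YFP-negative array 3 exchanged, and it points to a structure of the samples whose source stays open. At day 7 and for YFP-negative cells at day 14 against day 3 there are 10 splits each, so a share under 0.05 cannot be reached; the real splits gave 0 and the highest others 2 and 1.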
